A study of Mus musculus with 4 samples.

How the data were processed

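The deposited data covered 4 mouse arrays, 2 of MEF and 2 of PA6 cells, each read on an Illumina MouseRef-8 v1.1 BeadChip. Groups, passages and media were taken from the labels. Replicates were numbered in the order of the sample records and were not paired across groups.

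The main table held an unnormalized mean bead intensity per probe and array, on a linear scale, per the file headers. The lowest values lay between 45.8 and 53.8, which shows no subtracted background. A detection score from 0 to 1 accompanied each intensity per the file headers. It rose with the signal, so 1 minus the score was used as the detection p. The submitters' processing notes name BeadStudio 1.5. Its background and summary settings are not given in the sources used here. A second table of 24611 rows held a score that the authors had processed further, with values in 12949 rows and 11662 rows empty. Each of its columns had a mean of 0 and an SD of 1, with medians of -0.229, -0.264, -0.216 and -0.243. A z-score of the log signal within each array gave back every deposited intensity of the rows with values to 1 decimal, so its scale, centring and direction are known. The filter behind its empty rows stays unknown, and its row names match no probe column of the main table. Its rows were matched to probes by their 4 intensities instead: of 12949 rows with values, 12939 fitted 1 probe and took its gene name, and 10 fitted several and stayed unnamed.

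Probes were named through a RefSeq gene table (assembly GRCm38.p6), used for names only: of 24613 probes, 20509 were matched by accession and 3301 by symbol or synonym, 577 kept the symbol in the file and 225 had none. A probe annotated to another gene but named after 18S ribosomal RNA was left out. The probes stood for 18463 genes, 4345 of them with several probes. No genome was used here, so no coordinates are given and cross-hybridisation was not checked. Probes were not checked for strain variants between CF1 MEF and PA6 cells either, and such a variant can make a probe look absent in 1 group.

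Background was corrected with limma's normexp from the detection p (offset 16), and arrays were quantile normalized and put on the log2 scale. The 11143 probes with a score over 0.95 on at least 2 of the 4 arrays were kept. The probe with the highest mean level stood for its gene, giving 9052 genes, of which 8789 had a symbol. Of the 281 called genes, 40 had several tested probes, and in 4 of them the probes differed in sign. Groups were compared with lmFit and eBayes (2 residual degrees of freedom, 2.85 prior degrees of freedom, prior SD 0.317), two-sided, with the Benjamini-Hochberg adjusted p under 0.05. Differences are PA6 minus MEF, and an SE is the moderated one. The median difference over all genes was 0.03, and other scalings and backgrounds moved it by less than 0.1. Where a gene was detected on both arrays of one group and neither array of the other, its fold is given as "at least": the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest detected level (log2 5.45, 5.50, 5.57 and 5.55) and the gene's own value. This fold rests on group means and carries no error, so a single array of the bright group can lie below it. Fitted log2 differences of such genes, and of genes undetected on 1 array of a group, depend on the offset. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for tables and figures.

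Of 797 entries in 35 gene lists fixed before the data were examined, 780 were on the array. The 29 lists with at least 5 tested genes were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry. With an estimated correlation, which rests on 2 residual degrees of freedom, 0 of the 11 called lists held. By fry's directional test, Hox and MHC class I genes passed (adjusted p = 0.0450 for each), and by its mixed test 19 lists. Among the called lists, putting undetected genes at their bound changed the median of the neural list only. Ontology terms of 10 to 500 tested genes were tested with Fisher's exact test; the term text in the table was truncated at 255 characters in 8208 cells, so some terms are missing.

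The named genes followed a rule fixed before the data were examined. It took the 12 largest called differences in each direction among genes with a symbol and groups that did not overlap, all title factors, other candidates and sex-linked genes, and up to 4 members of each other list with the smallest adjusted p (the 2 largest differences where none was called). It also took the 5 largest folds among genes detected in 1 group alone. Genes outside it are marked as chosen after their values were seen. One gene that the rule takes is not reported here.

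The fit was tested on simulated data for this comparison: 20 runs of 9052 genes, with 200 changed genes per run, 50 at each fold. It recovered 0.1% of 2-fold, 14% of 4-fold, 68% of 8-fold and 86.1% of 16-fold changes, and 6.40% of all calls were false. The simulated variances were drawn from the fitted prior, whatever the level of a gene, and with no limit of detection. These rates therefore do not describe calls of genes undetected in 1 group, which were 41 of the higher and 127 of the lower calls. A list of 20 genes shifted by 1 log2 unit was called in 20 of 20 runs with the preset correlation and in 0 with the estimated one. With the preset correlation, 2 of 600 unchanged lists were called. Simulated genes varied independently, so that count says nothing about lists whose genes vary together. Among the 11 called lists the estimated correlation ran from -0.09 (MHC class I) to 0.58 (imprinted genes), and it was 0.52 for interferon-stimulated genes.

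Alternatives covered background correction, normalization, the offset, the filter on dim probes, the rule for several probes, the variance model, a fold requirement, passage as a covariate, the deposited score table and leaving out each array. The BeadChip as a block was not run, since the column names give no chip. Batch and group therefore could not be examined separately.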

Results

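Gene expression was measured in primary mouse embryonic fibroblasts (MEF, strain CF1) and in PA6 cells, a mouse stromal cell line. Total RNA from confluent dishes was hybridised to Illumina MouseRef-8 v1.1 BeadChips, one array per culture, with 2 arrays per group. The MEF arrays came from passage 2 (replicate 1) and passage 4 (replicate 2), and the PA6 arrays from passage 4 (replicate 1) and passage 5 (replicate 2). The study set PA6 cells, whose conditioned medium steers human pluripotent cells towards differentiation, against MEF as the control, and its title names the secreted factors SDF1alpha, sFRP1 and VEGFD. MEF were kept in DMEM and PA6 cells in MEM-alpha. Cell type, medium, origin as primary cells or as a line, and any difference in strain therefore went together. Median signals were 106.3 and 105.5 on the MEF arrays and 101.7 and 95.9 on the PA6 arrays. Of 24613 probes, 10897 and 10733 were detected on the MEF arrays and 10469 and 10548 on the PA6 arrays. The number of arrays limits the precision. Nothing in the labels says that the replicates came from separate isolations or thaws, so the p-values measure only the spread between these samples, which may be partly technical.

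The first comparison asked whether the secreted factors named in the title were more abundant in PA6 cells than in MEF. Cxcl12, which encodes the chemokine SDF1, was 4.83-fold higher in PA6 (log2 difference 2.27 ± 0.33, SE, 2 arrays per group; limma adjusted p = 0.0452). Its second probe gave a log2 difference of 3.77. Sfrp1, a secreted Wnt antagonist, had a log2 difference of 2.42 ± 0.93 (SE; adjusted p = 0.278), and Vegfd, a lymphangiogenic growth factor, one of 2.72 ± 1.08 (SE; adjusted p = 0.290). For all 3 genes both PA6 arrays lay above both MEF arrays, but Sfrp1 and Vegfd did not pass the test. Their PA6 arrays stood far apart, at 11.20 and 13.96 for Sfrp1 and 10.37 and 13.44 for Vegfd on the log2 scale, replicate 1 first. On these PA6 arrays the mitotic and S-phase genes also differed, with a median 1.37 log2 units lower on replicate 2.

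Of the 3 title factors, 1 was called over all genes tested and 1 adjusted over the list alone. The study may have chosen this list on these arrays, so neither count is independent evidence of its direction. Among other reported stromal candidates, Efnb1 differed by 1.74 ± 0.52 (SE; adjusted p = 0.191), Igf2 by -0.99 ± 0.69 (adjusted p = 0.544) and Ptn, the heparin-binding factor pleiotrophin, by -0.09 ± 1.11 (adjusted p = 0.979). None of these 3 was called, also when adjusted over the list alone, and their median (-0.09) and mean (0.22) differed in sign. The Cxcl12 call ended when any 1 array was left out: its adjusted p was 0.155 without MEF replicate 1, 0.242 without MEF replicate 2, 0.0950 without PA6 replicate 1 and 0.213 without PA6 replicate 2, and over all settings the range was 0.0294 to 0.268. Its log2 difference in those fits, in the same order, was 2.53, 2.02, 2.60 and 2.00, each with 1 residual degree of freedom. Without PA6 replicate 2 the log2 differences of Sfrp1 and Vegfd were 1.06 and 1.19, and without PA6 replicate 1 they were 3.81 and 4.27.

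**Figure D1:**
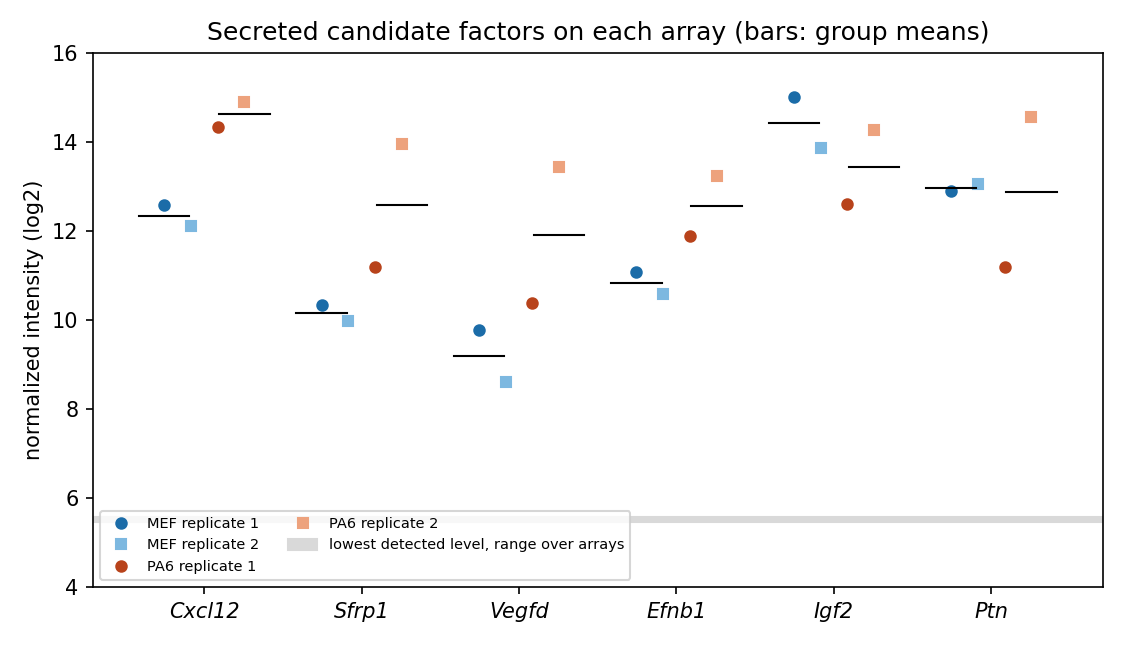
Normalized log2 intensity (vertical axis) of 6 secreted candidate factors (horizontal axis) on the 4 arrays; points are arrays, black bars are group means, and the grey band spans the lowest detected level of the arrays. Both PA6 arrays lie above both MEF arrays for Cxcl12, Sfrp1, Vegfd and Efnb1, while the PA6 arrays of Ptn lie on either side of the MEF arrays.

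Over all genes, the comparison asked which transcripts set PA6 cells apart from MEF. By fitted log2 difference, genes higher in PA6 were led by Slpi and Adh7. Slpi encodes a secreted protease inhibitor (at least 110-fold by group means, limma adjusted p = 0.0142). Its PA6 arrays stood at 11.30 and 13.21, replicate 1 first. Adh7 encodes an alcohol dehydrogenase that acts on retinol (at least 67.9-fold, limma adjusted p = 0.00626). Neither gene was above background on a MEF array, and the place of Adh7 before Cygb rests on such levels. Cygb, the globin cytoglobin, was higher by 6.54 ± 0.40 log2 units (SE), and the amine oxidase gene Aoc3, the xanthine oxidoreductase gene Xdh and the chemokine gene Ccl9 by 5.35 ± 0.75, 5.27 ± 0.33 and 5.09 ± 0.73. Hgf, which encodes hepatocyte growth factor, was higher by 4.42 ± 0.35, and the dipeptidase gene Dpep1 by 4.92 ± 0.32. Cygb, Xdh and Dpep1 were detected on 1 of the 2 MEF arrays. Their MEF values lay near or below the lowest detected levels (Cygb at 5.61 and 4.74), so their fitted differences depend on the offset. Otx1 and Dmrta2, both developmental transcription factor genes, were at least 19.8-fold and at least 22.4-fold higher. Csprs was at least 26.1-fold and Trim30a at least 24.6-fold higher.

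Genes lower in PA6 were led by Ndn, the imprinted gene of necdin, which was at least 169-fold lower (adjusted p = 0.00770), and Dkk3, a member of the Dickkopf family of secreted proteins, at least 97.6-fold lower (adjusted p = 0.00626). Gpnmb, Itm2a, Igfbp5 and Cdkn1c were at least 59.2-fold, 57.4-fold, 40.5-fold and 48.6-fold lower, and Crabp1, a retinoic acid binding protein gene, at least 40.7-fold. The 3 tested Gpnmb probes gave log2 differences from -6.62 to -1.99, and the fold is that of the brightest probe. Cd59a, which protects cells from complement lysis, was at least 33.4-fold lower. The galectin gene Lgals3 differed by -6.41 ± 0.78 log2 units (SE), the actin gene Acta1 by -5.57 ± 0.86 and Lrrc15 by -5.50 ± 0.68. Lgals3 and Acta1 were detected on 1 of the 2 PA6 arrays. Gpnmb and Lgals3 are abundant in macrophages, whose markers stood higher on MEF replicate 2, but their levels on the MEF arrays were 11.55 and 11.34, and 13.01 and 13.06. The brightest Hoxc6 probe stood at 12.34 and 11.79 on the MEF arrays and was not above background on the PA6 arrays (adjusted p = 0.00626), while a dimmer probe of the gene, detected in both groups, differed by 0.12.

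In all, 113 genes were higher and 168 lower in PA6 among 9052 tested (limma, Benjamini-Hochberg adjusted p under 0.05). That is 3.10% of the genes, and every called difference was at least 2-fold. Both PA6 arrays lay beyond both MEF arrays for 49.2% of tested genes, where chance gives 33.3%. Of the called genes, 41 were detected on both PA6 arrays and no MEF array, and 127 on both MEF arrays and no PA6 array. The median SD within a group was 0.0748 log2 units for genes not detected there and 0.245 for genes detected on all 4 arrays. When only probes detected on all 4 arrays were tested, 4 genes were higher and 2 lower. No gene was called when any 1 of the 4 arrays (MEF replicate 1 or 2, PA6 replicate 1 or 2) was left out, although 816 to 1370 then had an unadjusted p under 0.05, against 1621 with all arrays.

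Several Hox genes of the B and C clusters, transcription factor genes of regional identity along the body axis, were detected in MEF and not in PA6. Hoxb7, Hoxc9 and Hoxb5 were at least 25.6-fold, 16.1-fold and 13.9-fold lower in PA6 (adjusted p = 0.00770, 0.00770 and 0.00880). Of 21 tested Hox genes, 6 were lower, 0 higher and 15 not called, with 8 lower adjusted over the list alone. Among those not called, chosen after their values were seen, Hoxd10 and Hoxa9 were detected in MEF alone, at least 3.02-fold and 1.20-fold lower in PA6 (adjusted p over the list alone 0.00858 and 0.0462), and Hoxa3 in PA6 alone, at least 1.21-fold higher. Hoxa5, also chosen in this way, differed by 0.84 ± 0.80 log2 units (SE), Hoxb2 by 0.01 ± 0.39 and Hoxc8 by -0.04 ± 0.28. The list was lower as a set (camera adjusted p = 0.00591, median -0.20, mean -1.22), with adjusted p = 0.537 with an estimated correlation. Without MEF replicate 1 or MEF replicate 2 the list's direction turned to higher (adjusted p = 0.438 and 0.543), since genes detected on MEF arrays alone then failed the detection filter.

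**Figure D2:**
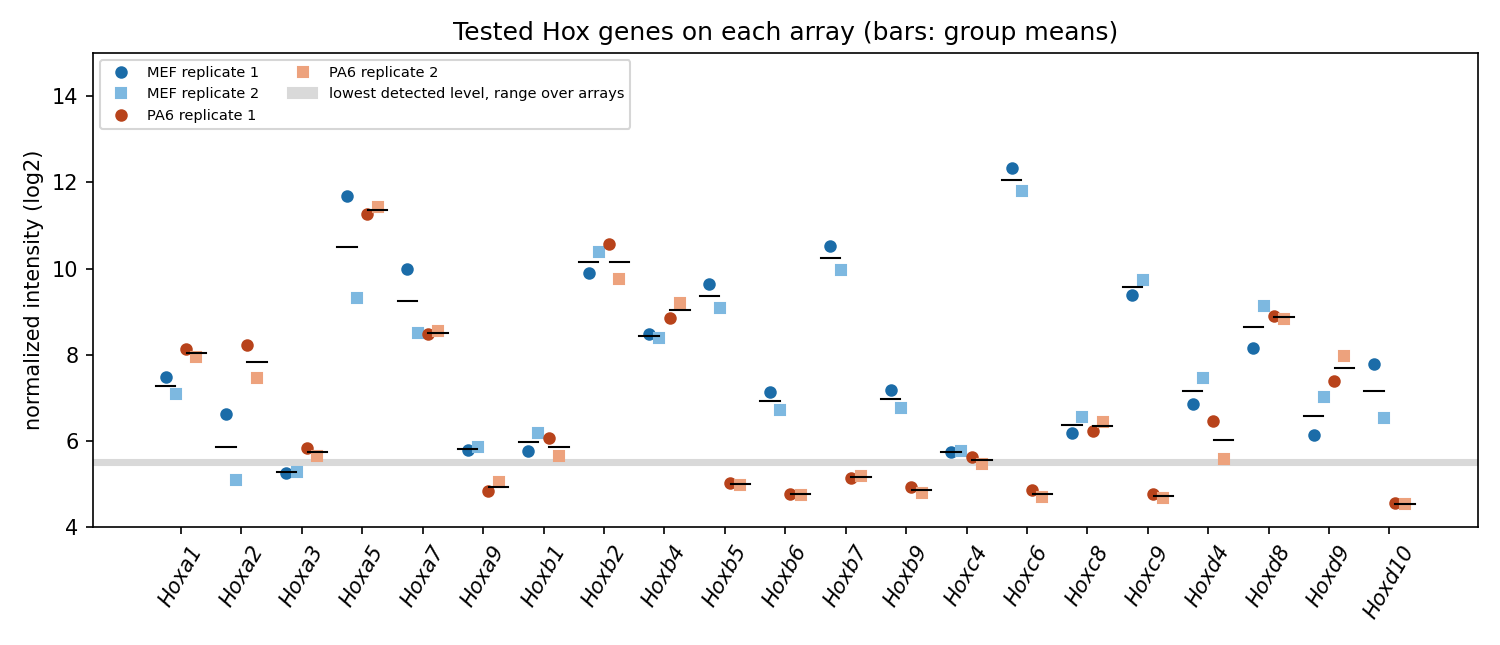
Normalized log2 intensity (vertical axis) of the 21 tested Hox genes (horizontal axis, by cluster) on the 4 arrays, 1 probe per gene; points are arrays, black bars are group means, and the grey band spans the lowest detected level of the arrays. Hoxb5, Hoxb7 and Hoxc9 lie below the band on both PA6 arrays and above a log2 level of 9 on both MEF arrays, while Hoxb2 overlaps between the groups; the Hoxc6 probe shown is the brighter of a pair that disagreed.

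Interferon-stimulated genes, the antiviral response set, were higher in PA6 as a set (camera adjusted p = 4.82e-13), with adjusted p = 0.601 with an estimated correlation. Of 25 tested, 5 were called higher and 0 lower, with 18 higher adjusted over the list alone, and the median log2 difference was 1.76. Ifit3, Gbp3 and Igtp (the last chosen after its value was seen) were higher by 3.11 ± 0.39, 3.12 ± 0.46 and 3.12 ± 0.46 log2 units (SE), and Oas2 and Oasl2 were at least 8.72-fold and 4.69-fold higher. Between the arrays of a group the list's median was 0.85 log2 units apart in PA6, lower on replicate 2, and 0.42 in MEF. MHC class I presentation genes had 2 of 10 tested genes higher, H2-T23 (1.78 ± 0.27) and the peptide transporter gene Tap2 (1.97 ± 0.31), 0 lower, and 4 higher adjusted over the list alone. Their median was 1.46 (camera adjusted p = 0.000257), with adjusted p = 0.537 with an estimated correlation. Ifit, Oas, Gbp and H2 genes have close paralogs, and no probe sequence was matched to a genome here, so signal shared between family members cannot be ruled out.

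Glycolysis and hypoxia genes were lower in PA6 as a set (median -0.52, camera adjusted p = 0.000134), with adjusted p = 0.537 with an estimated correlation. Of 23 tested, 2 were lower and 0 higher, with 6 lower adjusted over the list alone: the oxygen sensor gene Egln3 was at least 4.18-fold lower (adjusted p = 0.0142) and the enolase gene Eno1 differed by -2.18 ± 0.29 log2 units (SE; adjusted p = 0.0368). In the unfolded protein and amino acid stress list, 2 of 22 were lower and 0 higher, with 2 lower adjusted over the list alone. These were Vldlr, a lipoprotein receptor gene (at least 10.5-fold lower), and Cth, which makes cysteine from cystathionine (at least 2.999-fold lower), and neither is a chaperone gene. The list median was -0.76 (camera adjusted p = 0.00198), with adjusted p = 0.806 with an estimated correlation, and 0.0657 without MEF replicate 2. For cholesterol biosynthesis, 0 of 20 genes were called, also when adjusted over the list alone. Hsd17b7 differed by -1.55 ± 0.30 log2 units (SE; adjusted p = 0.0791). The set was lower with a median of -0.46 (camera adjusted p = 0.00591). Camera gave an adjusted p of 0.806 with an estimated correlation and 0.0651 with passage as a covariate. It did not call the set without PA6 replicate 2. Between the PA6 arrays the median of the set was 0.51 log2 units lower on replicate 2, no smaller than the group difference.

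In the insulin-like growth factor axis, the binding protein genes Igfbp5, Igfbp2 and Igfbp3 were at least 40.5-fold, 12.3-fold and 9.90-fold lower in PA6, and Igfbp4 was higher by 3.63 ± 0.41 log2 units (SE). Of 12 tested, 1 was higher and 3 lower, with 1 higher and 4 lower adjusted over the list alone. The list was lower (median -0.57, camera adjusted p = 0.0126), with adjusted p = 0.537 with an estimated correlation. Camera did not call it with detection on all 4 arrays (adjusted p = 0.420), or without MEF replicate 1, MEF replicate 2 or PA6 replicate 1. Igfbp5, Igfbp2 and Igfbp3, detected on MEF arrays alone, failed the detection filter in these settings, apart from the one without PA6 replicate 1. TGF-beta and BMP genes had 0 of 18 called and 1 lower adjusted over the list alone. The ligand genes Gdf10 and Gdf15 were not above background in PA6. By their group means they were at least 3.77-fold and 3.99-fold lower there, but not called (limma adjusted p = 0.155 and 0.223). Their MEF arrays were uneven, at 8.53 and 6.42 for Gdf10 and at 8.81 and 6.31 for Gdf15, replicate 1 first. That list was lower (median -0.56, camera adjusted p = 0.0249), with adjusted p = 0.537 with an estimated correlation. Its adjusted p was 0.0688 without PA6 replicate 1, 0.0577 with no filter on dim probes, 0.126 with detection on all 4 arrays and 0.0631 in the deposited score table.

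Chemokine genes were called in either direction: Ccl9, Cxcl12 and Cx3cl1 (1.65 ± 0.25) were higher and Cxcl14 at least 13.9-fold lower. Of 12 tested, 3 were higher and 1 lower, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.493). Without MEF replicate 2 the list was called higher. In that fit Cxcl14 and Cxcl1, both lower in PA6 and detected on MEF arrays alone, failed the detection filter. They also failed it without MEF replicate 1, where the list was not called. The filter alone therefore does not account for the call. Cxcl1 was chosen after its values were seen. Within MEF the chemokine median was 1.15 log2 units higher on replicate 2, the array with the macrophage markers. A link between the markers and the list was not tested. Among neurotrophic factors 1 of 12, Hgf, was higher and 1, the midkine gene Mdk (at least 7.69-fold), was lower, with the same counts adjusted over the list alone (camera adjusted p = 0.593). Of 11 Wnt ligands and modulators, Dkk3 was the 1 called gene, lower, and 2 were higher and 4 lower adjusted over the list alone (camera adjusted p = 0.509; median 0.41, mean -0.40). Of 7 VEGF and PDGF ligands, the lymphangiogenic factor gene Vegfc was at least 8.10-fold lower and none was higher, with 2 lower adjusted over the list alone (camera adjusted p = 0.732; median 0.19, mean -0.23). The axon guidance genes had 1 of 18 lower, Sema5a (-3.14 ± 0.32; a second probe gave -0.32), and the count adjusted over the list alone was also 1 (camera adjusted p = 0.473). Hematopoietic support factors had Cxcl12 higher and Il11 at least 5.28-fold lower among 9, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.638). Camera called this list higher among probes detected on all 4 arrays (adjusted p = 0.0255), and also without MEF replicate 2. In both settings Il11, detected on MEF arrays alone, failed the detection filter. Il11 also failed it without MEF replicate 1, where the list was not called. Just 2 FGF genes were tested, Fgf10 (-0.21 ± 1.24) and Fgf18 (0.02 ± 0.26), and 0 were called, also when adjusted over the list alone.

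**Figure D3:**
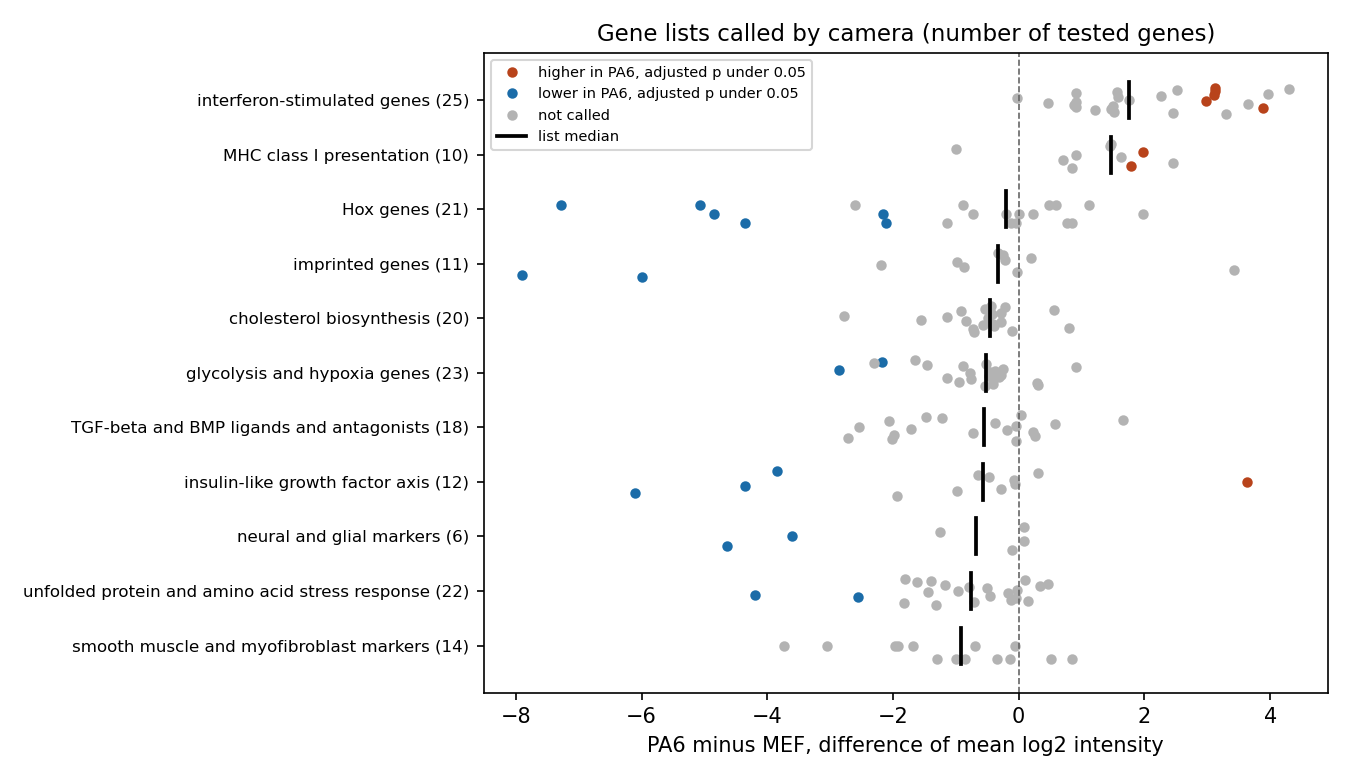
Log2 difference of PA6 minus MEF (horizontal axis) for the tested genes of the 11 lists called by camera with its preset correlation (vertical axis, number of genes in brackets); each point is a gene, coloured where called, and black lines are list medians. Medians were 1.76 for interferon-stimulated and 1.46 for MHC class I genes and below 0 for the other lists, and no list was called with an estimated correlation.

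Of 16 adipocyte and preadipocyte genes 0 were called; the preadipocyte factor gene Dlk1 differed by 3.43 ± 0.71 log2 units (SE; adjusted p = 0.0903) and the lipase gene Lpl by -3.21 ± 0.64 (adjusted p = 0.0839), and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.515). Of 13 osteoblast genes 0 were called and 2 were lower adjusted over the list alone (camera adjusted p = 0.493), with Spp1 at -2.87 ± 1.06 and Tnfrsf11b at -2.83 ± 0.64. Of 7 chondrocyte genes 0 were called, also when adjusted over the list alone (camera adjusted p = 0.515), with Matn4 at 5.14 ± 1.45 and Sox9 at 2.37 ± 0.56. Smooth muscle and myofibroblast genes had 0 of 14 called and 3 lower adjusted over the list alone. Of the contractile genes, neither of them called, Myh11 was at least 5.56-fold lower (adjusted p = 0.0566) and Tagln, detected on 1 PA6 array, differed by -3.74 ± 1.16 (adjusted p = 0.204). This list was lower (median -0.92, camera adjusted p = 0.00688), with adjusted p = 0.806 with an estimated correlation. It was not called without MEF replicate 2 or PA6 replicate 2. Between the arrays of a group, replicate 2 minus replicate 1, its median was -1.01 in PA6 and 0.71 in MEF. The one in PA6 was no smaller in size than the group difference. Of 6 skeletal muscle genes, Acta1 was lower, with 2 lower adjusted over the list alone (camera adjusted p = 0.0603). That list was called lower without MEF replicate 2 (adjusted p = 0.0408), without PA6 replicate 1 (0.0217), with median scaling (0.0420) and in the deposited score table (0.0460). Collagens had 0 of 17 called, also when adjusted over the list alone (camera adjusted p = 0.0603), with Col7a1 at -3.75 ± 0.75 and Col18a1 at -2.13 ± 0.69. The collagen list was called lower without MEF replicate 1 (adjusted p = 0.00762), with passage as a covariate (0.0317), with median scaling (0.0431), among probes detected on all 4 arrays (0.0391) and in the deposited score table (0.0319).

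Matrix proteases and inhibitors included Mmp23 and Mmp13, at least 23.9-fold and 23.1-fold lower in PA6, and Adamts5, higher by 2.01 ± 0.31 log2 units (SE). A second Mmp13 probe gave a log2 difference of -1.41, against -5.30 for the brighter one. Of 19 tested, 1 was higher and 2 lower, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.474). Among 11 complement genes, Cfb was at least 10.3-fold higher, while the protective surface protein genes Cd59a and Cd55 (at least 8.90-fold) and C2 (at least 5.31-fold) were lower. Adjusted over the list alone, 5 were higher and 3 lower; the median was 2.36 and the mean 0.60, camera's direction was up (adjusted p = 0.593) and fry's was down (adjusted p = 0.245). Camera called the list higher among probes detected on all 4 arrays (adjusted p = 0.0134), and also without MEF replicate 1 or MEF replicate 2. In each of these settings Cd59a, Cd55 and C2, detected on MEF arrays alone, failed the detection filter. The list was then tested without these lower genes. Of 11 imprinted genes, Ndn and the cyclin-dependent kinase inhibitor gene Cdkn1c were lower, with 1 higher and 2 lower adjusted over the list alone. That list was lower (median -0.33, camera adjusted p = 0.0339), with adjusted p = 0.806 with an estimated correlation. Between the arrays of a group, replicate 2 minus replicate 1, its median was 0.86 in PA6 and -0.67 in MEF. Both were larger in size than the group difference. Camera did not call the list with the mean of probes (adjusted p = 0.0579), the dimmest probe (0.141) or detection on all 4 arrays (0.516). It was not called without MEF replicate 1, MEF replicate 2 or PA6 replicate 1 either. Ndn and Cdkn1c, detected on MEF arrays alone, failed the detection filter when 1 MEF array was left out and with detection on all 4 arrays.

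For proliferation, 0 of 37 mitotic and S-phase genes were called, also when adjusted over the list alone (camera adjusted p = 0.531), with Rrm1 at 1.24 ± 0.65 log2 units (SE) and Ccne2 at -1.14 ± 0.84. Within PA6 these genes were lower on replicate 2 for 36 of the 37. With the preset correlation the list was called higher in PA6 without PA6 replicate 2 and lower without PA6 replicate 1. It was also called lower without MEF replicate 1. Its genes varied together, with an estimated correlation of 0.80 and a camera adjusted p of 0.901 with it. These calls therefore follow single arrays and do not tell the groups apart. Of 23 p53 targets and cell cycle inhibitors, Cdkn2c was higher (2.09 ± 0.27) and Cdkn1c lower, with the same counts adjusted over the list alone (camera adjusted p = 0.647), and the list was called lower without MEF replicate 2 (adjusted p = 0.0408) or PA6 replicate 2 (0.0311). Immediate-early genes had 0 of 19 called, also when adjusted over the list alone (camera adjusted p = 0.515), with Fosb, not above background in MEF, at least 1.64-fold higher (adjusted p = 0.223) and Egr2 at 1.06 ± 1.32. Without PA6 replicate 1 they were called lower as a set (adjusted p = 0.00115).

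Of 19 blood cell and macrophage markers on the array, 14 were detected on MEF replicate 2, 5 on MEF replicate 1 and 1 on both PA6 arrays. The macrophage lysozyme gene Lyz2 stood at 6.22 on MEF replicate 1 and 12.87 on MEF replicate 2, and Laptm5 at 8.92 and 12.67. Of the 6 tested, 0 were called and 1 was lower adjusted over the list alone (median -2.35, camera adjusted p = 0.0603). Camera called this list lower with median scaling (adjusted p = 0.0235), no filter on dim probes (0.00163) and the deposited score table (0.00792). It also did so with passage as a covariate (adjusted p = 4.20e-08) and without PA6 replicate 2. These calls used the preset correlation. The estimated correlation was 0.94, and the camera adjusted p with it was 0.806. Within MEF the list's median was 3.21 log2 units higher on replicate 2, more than the group difference. The calls therefore cannot separate a group difference from that 1 array. Of 6 neural and glial markers, the intermediate filament gene Nes (at least 6.87-fold) and the growth cone gene Gap43 (at least 14.9-fold) were lower, with 3 lower adjusted over the list alone. The list was lower (median -0.68, or -0.24 with undetected genes at their bound; camera adjusted p = 0.0239), with adjusted p = 0.537 with an estimated correlation, 0.0580 without PA6 replicate 1, 0.0619 with no filter on dim probes and 0.0631 in the deposited score table. Of 6 endothelial markers, Sox18 was at least 2.63-fold higher, also the 1 call adjusted over the list alone (camera adjusted p = 0.509, direction down; fry's direction was up, adjusted p = 0.944), and without MEF replicate 2 camera called the list lower (adjusted p = 0.0401). Of 3 epithelial markers 0 were called and 1 was higher and 1 lower adjusted over the list alone, with Krt7 at -2.39 ± 0.62 and Trp63 at 1.95 ± 0.52 log2 units (SE). No erythroid marker passed the detection filter. Of 3 tested Y-linked genes 0 were called, with 2 higher and 1 lower adjusted over the list alone. Eif2s3y, detected on 1 MEF array, differed by 4.69 ± 0.87 (adjusted p = 0.0714). Ddx3y, detected in PA6 alone, was at least 1.98-fold higher (adjusted p = 0.0739) and Kdm5d, detected in MEF alone, at least 1.61-fold lower (adjusted p = 0.215).

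Among the ontology terms that the deposited table gives per probe, 184 were tested against 5610 genes. Of the lower genes with a term, 8 lay among the 84 extracellular genes (1.74 expected), 10 among the 136 plasma membrane genes (2.81 expected) and 5 among the 33 growth factor activity genes (0.682 expected), each with an adjusted p of 0.0318 by Fisher's exact test. Of the higher genes, 0 terms were enriched. Without any 1 of the 4 arrays, MEF replicate 1 or 2 or PA6 replicate 1 or 2, 0 terms were enriched among lower genes, since no gene was then called. The count of lower terms was 1 with median scaling and 0 with no background correction, with either alternative of offset 50, with no filter on dim probes, with detection on all 4 arrays, with passage as a covariate, with z-scores and in the deposited score table.

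Arrays of the same group resembled each other more than arrays of different groups. Across genes, which are not independent replicates, Pearson's r was 0.943 between the MEF arrays and 0.947 between the PA6 arrays, against 0.833 to 0.884 between groups. The SD of the log2 difference between arrays was 0.720 in MEF and 0.701 in PA6, and 1039 and 1088 of the 9052 genes were over 2-fold apart. Passage differed within each group with 1 array per passage, so these differences are values without a test. Among the genes furthest apart, chosen after their values were seen, the cartilage collagen gene Col2a1 stood at 10.65 and 5.04 on the MEF arrays, and the haptoglobin gene Hp at 8.24 and 13.57 on the PA6 arrays.

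**Figure D4:**
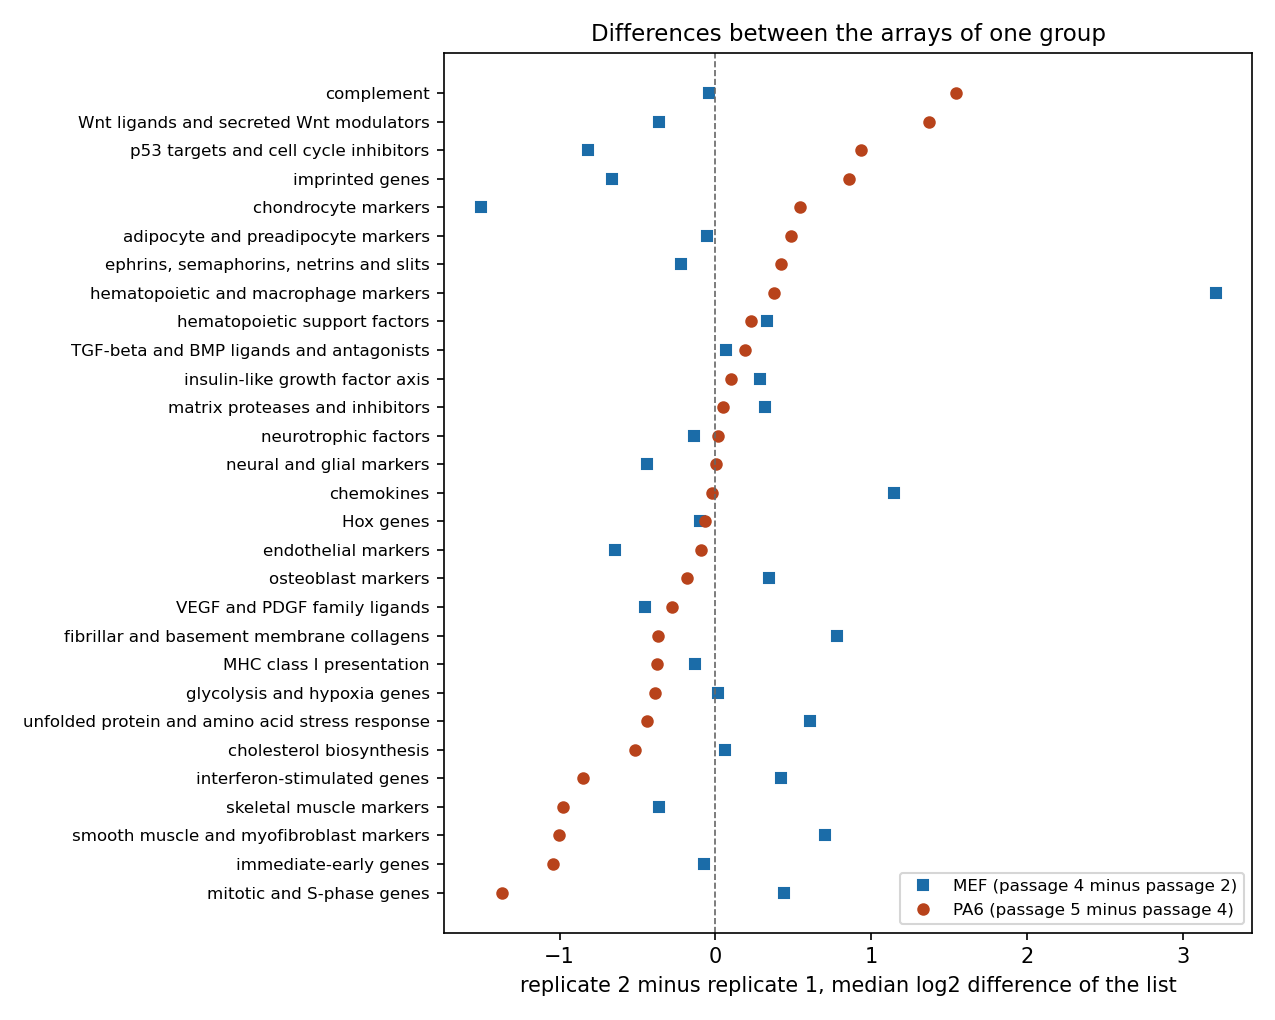
Median log2 difference between the arrays of a group, replicate 2 minus replicate 1 (horizontal axis), for each tested gene list (vertical axis); blue squares are MEF and orange circles PA6, 1 pair of arrays each, with no test. Macrophage markers stand at 3.21 in MEF, and mitotic genes at 0.44 in MEF and -1.37 in PA6.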

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

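The z-scores of the log signal were the alternative chosen only after the data were seen. Against 113 higher and 168 lower genes, counts moved by over 1.5 times with no background correction (39 higher, 79 lower), normexp by saddlepoint with offset 50 (42, 83), the offset of 50 (41, 77), no filter on dim probes (22, 47), detection on all 4 arrays (4, 2), treat against 1.5-fold (44, 96), z-scores of the log signal (41, 78) and the deposited score table (33, 61 by gene; 32, 58 by probe). The cause of these moves was not tested. With passage as a covariate, and without each array, 0 genes were higher and 0 lower by limma (range 0 to 0), with 864 and 816 to 1370 genes at an unadjusted p under 0.05; these fits have 1 residual degree of freedom, and the lone array of a group is assumed to vary like the other group. Of the called genes still tested, 153 of 154 and 152 of 154 kept their direction without MEF replicates 1 and 2. Without PA6 replicates 1 and 2, 239 of 239 and 240 of 240 did so. All called genes differed by at least 1.58 log2 units on these same arrays, so their kept direction was largely fixed in advance. The share of higher calls was 40.2%, and a scaling to equal medians gave 43.4%.

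The number of title factors called fell from 1 to 0 with no background correction, saddlepoint with offset 50, offset 50, no filter, detection on all 4 arrays, treat, passage, z-scores, the deposited score table and without each array (range 0 to 0); all 3 stayed higher in PA6. Lists called fell from 11 to 0 with an estimated correlation, 2 passed fry's directional test and 19 its mixed test. Interferon, MHC class I and glycolysis lists were called in 18 of 18 other settings of the data, the stress list in 17, smooth muscle and cholesterol in 16, Hox in 15, TGF-beta and insulin-like growth factor in 14 and imprinted genes in 12, and the neural list in 11 of 14. Enriched terms among lower genes fell from 3 to 1 with median scaling and to 0 with no background correction, saddlepoint with offset 50, offset 50, no filter, detection on all 4 arrays, passage, z-scores, the deposited score table and without each array (range 0 to 0). Pearson's r across genes was 0.949 in MEF and 0.948 in PA6 with no background correction, 0.954 and 0.957 in the deposited score table, and 0.948 and 0.937 over genes detected on all 4 arrays.

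Some directions reversed. Hoxc6 was 0.12 with detection on all 4 arrays and with the dimmest probe, 0.19 without MEF replicate 1 and 0.04 without MEF replicate 2, since its dimmer probe then stood for the gene (range without each array -7.31 to 0.19). Without each array Ptn ranged from -1.79 to 1.62 (above 0 without MEF replicate 2 or PA6 replicate 1), Fgf10 from -2.10 to 1.70 and Egr2 from -0.88 to 3.02 (both turned without PA6 replicate 1), and Fgf18 from -0.0866 to 0.132 (below 0 without MEF replicate 2 or PA6 replicate 2). Fgf18 was also -0.0412 with median scaling and -0.0122 as z-scores. None of Ptn, Fgf10, Fgf18 and Egr2 was called, and the cause was not tested. The Hox list turned to higher with detection on all 4 arrays (adjusted p = 0.609) and without MEF replicate 1 (0.438) or MEF replicate 2 (0.543), with a range of 0.00364 to 0.543 without each array. The mitotic list turned to higher without PA6 replicate 2 (0.000626), with a range of 2.96e-05 to 0.852. No paired analysis was possible because the groups share just 1 number in their titles: these begin with 6 and 1 for MEF and 1 and 2 for PA6, in replicate order. The chip as a block was not run. Signal over background limits the rest: 87 of the 281 called genes were detected on all 4 arrays. When only probes detected on all 4 arrays were fitted, 89 of the 281 had such a probe, and 6 of these stayed called. Most calls of genes detected on all 4 arrays thus depended on which other probes were fitted.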

Other observations

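Tests chosen only after the result was seen were those of the single PA6 array, blood cells in PA6 and the culture medium. Between the arrays of a group, whole gene groups stood apart, here given as replicate 2 minus replicate 1 with no test. In PA6 the complement list had a median of 1.55 log2 units, Wnt ligands and modulators 1.37, p53 targets and cell cycle inhibitors 0.93 and imprinted genes 0.86, while mitotic genes stood at -1.37, immediate-early genes at -1.04, smooth muscle genes at -1.01 and skeletal muscle genes at -0.98. C3, the central complement component, was at 10.31 and 13.64 on the PA6 arrays and at 5.78 and 6.54 on the MEF arrays (adjusted p = 0.0791), a gene chosen after its values were seen. In MEF, chondrocyte genes stood at -1.51, p53 targets at -0.82, imprinted genes at -0.67 and endothelial markers at -0.65, and collagens at 0.78, smooth muscle genes at 0.71, the stress list at 0.61 and mitotic genes at 0.44. Medians of the mitotic, p53 and smooth muscle lists lay at percentile 0 or 100 of 10000 random lists of their size and mean level in both groups. Those of several other lists did so in 1 group. Genes of a random list need not vary together, while the mitotic, p53 and smooth muscle lists had estimated correlations of 0.80, 0.63 and 0.45. Such percentiles are therefore only a description of these arrays.

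The first pattern is the higher level of interferon-stimulated genes in PA6. A single deviating PA6 array is argued against, since 23 of 25 tested genes had both PA6 arrays above both MEF arrays. Scaling and background correction are argued against too, as the lowest median over those settings was 1.38 log2 units. Blood cells in the PA6 cultures are argued against, since 1 of 19 blood cell and macrophage markers was detected on both PA6 arrays. Culture medium cannot be told apart from cell type, because 0 cell types were kept in both media. Any difference in strain cannot be told apart from cell type either.

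The second pattern is the set of macrophage genes on MEF replicate 2. Of 19 markers, 14 were at least 1 log2 unit higher there than on MEF replicate 1. A second list of macrophage genes was written once this was known, but before its own values were seen. Of its 22 genes on the array and in no earlier list, 13 were at least 1 log2 unit higher on MEF replicate 2, against 3.25% of all genes on the array, which is consistent with macrophages in that culture. With 3 C1q genes of the second list, left out because their detection had been seen, the count was 16. Abundant macrophage genes, chosen after their values were seen, stood at 4.77 and 10.37 (Fcer1g) and at 5.10 and 10.33 (Adgre1) on MEF replicates 1 and 2. Scaling is argued against, since 14 markers were still at least 1 log2 unit higher with arrays scaled to equal medians. Passage, 2 against 4, stays open as an untested explanation, with 1 array each.

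The third pattern is the higher level of the title factors on PA6 replicate 2 than on replicate 1, by 0.55 log2 units for Cxcl12, 2.76 for Sfrp1 and 3.07 for Vegfd. A more slowly cycling culture is a candidate explanation: the mitotic and S-phase list had a median of -1.37 between these arrays, with 36 of 37 genes lower on replicate 2. That test shows only lower levels of mitotic transcripts on 1 array, not slower cycling itself, nor that it raised the factors. Other lists also stood apart between these arrays, such as complement at 1.55 and Wnt ligands and modulators at 1.37. Scaling is argued against as the whole explanation, since 2 of the 3 factors were still at least 0.5 log2 units higher with arrays scaled to equal medians, where Cxcl12 differed by 0.40. Passage, 4 against 5, stays open as an untested explanation.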
